A study of Mus musculus with 9 samples.

How the data were processed

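Total RNA of mouse bone-marrow-derived dendritic cells was measured on 9 Illumina expression arrays, 3 from uninfected cells (Control), 3 from cells infected with Aggregatibacter actinomycetemcomitans (Aa) and 3 from cells infected with Porphyromonas gingivalis (Pg). Groups and replicate numbers were taken from the labels. The labels do not say whether the arrays of a group came from separate animals or cultures, so the p-values measure the spread between these samples.

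The values used are the log2 signals deposited by the authors, 1 per probe and array. limma was used by the authors, per the submitters' processing notes, which give no version, and how the values were normalized is not given in the sources used here. The quantiles of the 9 arrays were nearly identical (medians 4.619 to 4.621), and the lowest values lay at 4.185 to 4.191, near the 4 that an offset of 16 leaves on the log2 scale. The design written before the data were examined named the table of raw signals as the source. Its 9 columns of signals carry names that match no sample label, so none of them was used, and the deposited log2 values took their place. No detection p-values could be used, so whether a low signal lies above background was not tested. For arrays, their number limits the precision.

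Of 45281 probes, 34885 paired with 1 gene, 18 with several and 10378 with none. Symbols of 34807 probes were updated through their Entrez identifiers from a table of mouse genes of assembly GRCm38.p6, which was used for names alone. Probes above the median of their array on at least 3 arrays were kept (26801, of which 21791 had 1 gene), and the probe with the highest mean over the 9 arrays stood for its gene, which left 13706 genes. Probes of near-identical family members, such as MHC class I, p200, Gbp and Oas genes, may bind each other's transcripts, and values of these genes are uncertain.

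A linear model with 1 mean per group was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3 (statmod 1.5.0), and the spread was moderated across genes (prior degrees of freedom 7.23, residual degrees of freedom 6). The 3 contrasts were Aa against Control, Pg against Control and Aa against Pg, each two-sided with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The last contrast is also the test of the difference between the effects of the infections. Genes are described as higher, lower, risen or fallen where they passed that threshold.

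Before the data were examined, 37 lists with 759 members were written, of which 698 were on the array and 615 were tested. They cover pro-inflammatory cytokines, anti-inflammatory and feedback regulators, chemokines, chemokine and adhesion receptors, type I interferon response, interferon-gamma-inducible GTPases and effectors, MHC class I and class II presentation, dendritic cell maturation and co-stimulation, pattern recognition, inflammasome, NF-kB, antimicrobial and oxidant effectors, and eicosanoids. Further lists cover glycolysis, the tricarboxylic acid cycle, respiratory chain, cholesterol synthesis, lipid handling, cell cycle, apoptosis, hypoxia, endoplasmic reticulum stress, oxidative stress, proteases and matrix, complement, osteoclast differentiation, and lysosome and phagosome. The last group holds M2-associated, macrophage, dendritic cell, neutrophil, mast cell, lymphocyte, erythroid and fibroblast markers and reference genes. Shifts were tested with camera of limma with a preset correlation of 0.01 between genes and adjustment over 111 tests, and again with an estimated correlation and with fry. Some genes are in several lists, such as Lcn2 (antimicrobial, neutrophil), Pparg (lipid, M2), Il1b (cytokine, inflammasome), Cd14 (pattern recognition, macrophage), Lyz2 (antimicrobial, macrophage) and Ciita (MHC class II, dendritic cell). A list of platelet genes and a list of further NRF2 targets were written after the main comparisons and before their own tests.

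The genes named follow a rule fixed with the design. It names per contrast the 10 higher and 10 lower genes with the largest change whose groups do not overlap, up to 4 members of each list, the 10 genes changed in opposite directions with the largest difference, and 12 genes set in advance, of which Il12b did not pass the filter. The Results describe only part of these genes, and the rule does not set which. Left out are, among others, Slc46a3, Lrrc14b, Angptl4, Vnn3 and Ccnd2. Signals of Ccnd2 were 10.64 to 10.97 with Aa and 5.46 to 6.00 in uninfected cells. Members named beyond this rule, because a count was 5 or fewer or a value in 1 comparison was set beside another, were chosen after their values were seen.

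Overlap of the infections was compared with independent lists and with 100 simulations of unchanged groups against the same uninfected arrays. The steps were tested on simulated data with 13706 genes, of which 200 were changed in Aa and 200 others in Pg. Both sets differ between Aa and Pg, so that comparison held more changed genes. A true log2 change of 0.5 was recovered for 34.3% of genes in Aa against Control, 35.8% in Pg against Control and 50% in Aa against Pg, and changes of 1 and 2 for 100% in each. False calls made up 6%, 4.3% and 8.3% of calls. Far fewer genes were changed in the simulated data than were called in the real data (3454 with Aa and 1457 with Pg). Errors were also drawn independently for each gene, so the shares recovered and falsely called may differ in the real comparisons. Alternatives fixed before the data were examined were other filters on dim probes, other ways from probe to gene, a replicate block, a trended robust moderation, array weights, a fit to the 2 groups compared, and leaving out each array in turn. A larger offset, no offset, arrays centred on the tested genes and cyclic loess were added after seeing the data.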

Results

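Total RNA of mouse bone-marrow-derived dendritic cells (BMDCs), antigen-presenting cells raised from C57BL/6 marrow with the growth factor GM-CSF (20 ng/ml for 6 days), was measured on Illumina expression arrays. Of the 9 arrays, 3 came from uninfected cells, 3 from cells given Aggregatibacter actinomycetemcomitans (Aa, strain Y4) and 3 from cells given Porphyromonas gingivalis (Pg, strain 381). Both are Gram-negative bacteria of the mouth that are linked with periodontitis. Infection lasted 24 h at a multiplicity of infection of 10. Log2 signals of 13706 genes were compared, and the number of arrays limits the precision, with a median standard error of 0.139 for a log2 change. Values after ± are standard errors of log2 changes with n = 3 arrays per group, unless SD is named. Square brackets give the change with the probes of the gene averaged, or with another offset, where these moved it by over 1.5 times, and cover only the genes followed through the other settings. Arrays of the same group correlated across genes at r = 0.9916 to 0.9929, with genes as the points, which are not independent replicates. Aa arrays correlated with uninfected arrays at r = 0.9578 to 0.9618, Pg arrays with uninfected arrays at r = 0.9781 to 0.9805, and Aa with Pg arrays at r = 0.9771 to 0.9802. The first principal component held 58.5% of the variance and placed the Pg arrays (mean score -0.9) between the uninfected (-34.1) and the Aa arrays (35.1). The next component held 16% and set the Pg arrays (20.8) apart from the uninfected (-10.8) and the Aa arrays (-10). Each list of genes named here was fixed before the data were examined, and the adjusted p beside its counts is that of camera. It tests whether the members as a set shifted in 1 direction, up or down, relative to the other genes. Members that moved both ways can cancel, so a list without a call may still hold many changed genes. Of the 52 shifts that camera called over the 3 comparisons, 25 were lost with an estimated correlation, and each of these is given with that value. The estimate lay above the preset 0.01 for some of these lists, such as macrophage markers (0.28), and below it for others, such as chemokines (-0.035). A larger correlation is thus not what ended the calls of the latter.

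**Figure D1:**
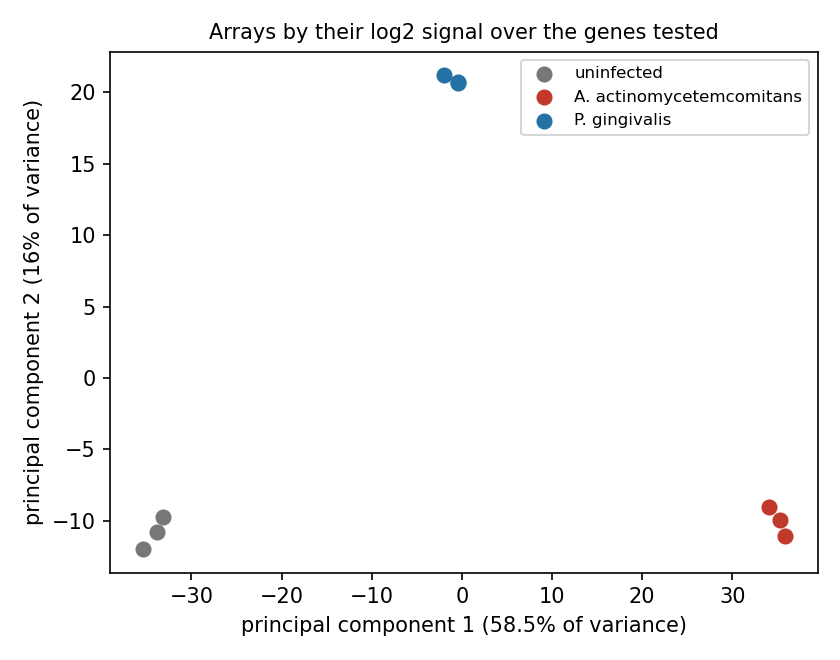
Principal components of the 13706 genes over the 9 arrays, with the scores of the first component (58.5% of the variance) on the x axis and of the next (16%) on the y axis. Each point is 1 array coloured by group, and the 3 groups do not overlap.

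The comparison of Aa-infected with uninfected cells asks what this bacterium changes in dendritic cells. Lcn2, an iron-scavenging antimicrobial protein, rose 88.9-fold (log2 change 6.47 ± 0.20, n = 3 arrays per group, adjusted p = 7.1e-11). The neutrophil-attracting chemokines Cxcl1 and Cxcl2 rose 55.3-fold and 55.0-fold, the interferon-induced ubiquitin-like protein Isg15 43.9-fold, the anti-inflammatory cytokine Il10 42.7-fold and the cytokine Il6 30.5-fold. The complement chains C1qb and C1qc fell by 3.78 ± 0.13 and by 3.74 ± 0.13 on the log2 scale. The chemokine Ccl6 fell by 4.0 ± 0.14, and the adhesion receptor gene Adgre5 by 4.04 ± 0.18. Ch25h, which makes an oxysterol from cholesterol, and Pld4, an endolysosomal nuclease, had log2 changes of -3.91 ± 0.11 and -3.82 ± 0.12.

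Inflammatory mediators rose with Aa. Of the pro-inflammatory cytokines, 12 of 14 rose and 0 fell (13 and 0 adjusted over the list alone, adjusted p = 3.14e-17). They include Il1a (5.02 ± 0.15), Tnf (4.27 ± 0.15), Il1b (4.19 ± 0.12) and Il23a, a subunit of interleukin 23 (4.23 ± 0.14 [probe mean 2.43]). Inhba, a subunit of activin A, also rose (5.01 ± 0.15). Among anti-inflammatory and feedback regulators, 10 of 16 rose and 2 fell (12 and 3 adjusted over the list alone, adjusted p = 4.75e-07). The signalling suppressors Socs3 (4.59 ± 0.15) and Cish (2.76 ± 0.12) and the interleukin 1 decoy receptor Il1r2 (3.95 ± 0.13) rose with Il10, while the mRNA-decay factor Zfp36 (-0.71 ± 0.12) and the receptor gene Il10ra (-0.56 ± 0.13) fell. Chemokines went both ways, with 10 and 4 of 18 (10 and 5 adjusted over the list alone, adjusted p = 0.00474) higher and lower and adjusted p = 0.0568 with an estimated correlation. Ccl4 rose (3.80 ± 0.15), and Ccl6, Ccl9 (-2.68 ± 0.12), Ppbp (-2.24 ± 0.18 [larger offset -1.33, no offset -3.80]) and Ccl7 (-0.67 ± 0.13) fell. Of NF-kB components and targets, 10 of 17 rose and 2 fell (10 and 2 adjusted over the list alone, adjusted p = 2.25e-05). The nuclear regulator Nfkbiz (3.90 ± 0.13) and the inhibitors Tnfaip3 (2.37 ± 0.14) and Nfkbia (1.99 ± 0.12) rose, and Relb (-0.75 ± 0.11) and Tnfaip2 (-0.50 ± 0.11) fell. Of the maturation and co-stimulation genes, 16 of 22 rose and 1 fell (17 and 1 adjusted over the list alone, adjusted p = 4.87e-13), and Relb was the member that fell. Cd70 (3.30 ± 0.12), Cd86 (2.93 ± 0.12) and Cd80 (2.89 ± 0.12), which signal to T cells, were higher, as was Cd40 (1.76 ± 0.11). Ccr7, the receptor that guides dendritic cells to lymph nodes, was at 0.42 ± 0.16 (adjusted p = 0.0639), and over the other settings its adjusted p ran from 0.0053 to 0.224. It passed without Pg 2 (adjusted p = 0.0345), without Pg 3 (adjusted p = 0.0426) and in 7 other settings.

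Antimicrobial and oxidant effectors and hypoxia response genes were higher as lists with the preset correlation. For the effectors 12 of 19 rose and 3 fell (13 and 3 adjusted over the list alone, adjusted p = 9.45e-06), and the call had adjusted p = 0.0941 with an estimated correlation. Beside Lcn2, the acute-phase gene Saa3 (4.02 ± 0.11), the arginine transporter gene Slc7a2 (4.0 ± 0.14 [probe mean 2.18]), the protease inhibitor gene Slpi (3.19 ± 0.14) and the nitric oxide synthase gene Nos2 (1.25 ± 0.13 [probe mean 0.66, larger offset 0.65, no offset 2.39]) rose, and Lyz2, Ass1 and Cyba fell. In the hypoxia list, 10 of 15 rose and 0 fell (10 and 0 adjusted over the list alone, adjusted p = 4.86e-07), with adjusted p = 0.0941 with an estimated correlation. Ndrg1 (2.80 ± 0.14) and Ddit4 (2.5 ± 0.13), which are also induced by other stresses, and Egln3 (2.04 ± 0.28), an oxygen-sensing hydroxylase, were among its increases. Egln3 was highest on Aa 2 (8.10 against 6.79 and 6.78), as was P4ha2 (9.07 against 8.28 and 7.98), and the list kept its call without that array.

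Interferon-induced genes rose with Aa. Of the type I interferon list, 20 of 26 rose and 1 fell (21 and 1 adjusted over the list alone, adjusted p = 3.42e-13), and Mx1 (-0.80 ± 0.19) was its decrease. Beside Isg15, the antiviral genes Oasl1 (3.40 ± 0.19) and Rsad2 (3.35 ± 0.16) and the ubiquitin ligase gene Trim30a (3.02 ± 0.19) rose. Ifi205, a member of the p200 gene family that lies outside the list, rose by 4.77 ± 0.15 [probe mean 2.70], a value its near-identical relatives leave uncertain. Of interferon-gamma-inducible GTPases and effectors, 11 of 20 rose and 2 fell (11 and 3 adjusted over the list alone, adjusted p = 1.77e-05). Gbp5 (4.03 ± 0.22 [probe mean 2.32]) and Ifi47 (2.82 ± 0.14) were higher and the antibody receptors Fcgr4 (-1.87 ± 0.12) and Fcgr1 (-0.81 ± 0.16) were lower. MHC class I presentation genes shifted up, with 10 and 2 of 19 (11 and 2 adjusted over the list alone, adjusted p = 0.000616) higher and lower. The peptide transporter genes Tap2 (1.02 ± 0.12) and Tap1 (0.89 ± 0.14) rose, and the chaperones Calr (-0.82 ± 0.12) and Pdia3 (-0.49 ± 0.13) fell. For MHC class II presentation, 9 of 14 rose and 2 fell (9 and 2 adjusted over the list alone, adjusted p = 0.0189), and the call had adjusted p = 0.109 with an estimated correlation. The master regulator Ciita (1.51 ± 0.13) and H2-Ob (1.39 ± 0.22 [larger offset 0.78, no offset 2.45]), an inhibitor of peptide loading, rose, and the endosomal enzymes Lgmn (-1.34 ± 0.12) and Ifi30 (-1.30 ± 0.12) fell.

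Genes of lysosomes and lipid handling were lower with Aa. In the lysosome and phagosome list, 2 of 22 rose and 15 fell (2 and 16 adjusted over the list alone, adjusted p = 7.51e-06). Lamp1 (-1.40 ± 0.11), Ctsl (-1.27 ± 0.14 [larger offset -0.62, no offset -2.88]) and Cd63 (-1.17 ± 0.12) were lower and Ctsc (0.54 ± 0.12) and Tfeb (0.43 ± 0.13) were higher. For lipid uptake, storage and efflux, 1 of 19 rose and 10 fell (1 and 10 adjusted over the list alone, adjusted p = 1.89e-06). The lipid-sensing receptor gene Pparg (-3.39 ± 0.17 [no offset -5.13]), the lysosomal lipase gene Lipa (-3.09 ± 0.12), Apoe (-2.41 ± 0.16) and the lipase gene Lpl (-1.88 ± 0.14 [probe mean -1.03]) fell, and the transfer protein gene Pltp (0.55 ± 0.14) rose. Tricarboxylic acid cycle genes gave 4 and 9 of 18 (4 and 11 adjusted over the list alone, adjusted p = 0.0282) higher and lower, with adjusted p = 0.301 with an estimated correlation. Idh1 (-2.11 ± 0.12) and Sdhc (-0.85 ± 0.12) fell, and Sdhd (1.06 ± 0.22) and Mdh1 (0.98 ± 0.13) were among the members that rose. The call of this list ended without Control 2 (adjusted p = 0.0669, range over the other settings 0.0129 to 0.0669). Markers of macrophages and monocytes moved with these lists: 2 of 12 rose and 9 fell (2 and 9 adjusted over the list alone, adjusted p = 5.31e-05), with adjusted p = 0.169 with an estimated correlation. The clearance receptor gene Mertk (-2.04 ± 0.21 [larger offset -1.28]) fell with the C1q chains, whereas the lipopolysaccharide co-receptor gene Cd14 (2.32 ± 0.14) and the adhesion receptor gene Adgre1 (0.70 ± 0.14) rose. Of M2-associated markers, 0 of 12 rose and 3 fell (0 and 4 adjusted over the list alone, adjusted p = 0.0417), with adjusted p = 0.136 with an estimated correlation. The decreases were those of Pparg, the mannose receptor gene Mrc1 (-3.21 ± 0.20) and the scavenger receptor gene Stab1 (-1.40 ± 0.13). That call ended without Aa 1 (adjusted p = 0.0797), without Control 3 (adjusted p = 0.0575) and with either other offset, and its adjusted p ranged from 0.0259 to 0.0808.

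The other lists had no shift past the threshold with Aa, although members of most of them changed. Pattern recognition receptors and adaptors gave 6 and 9 of 29 (7 and 9 adjusted over the list alone, adjusted p = 0.837) higher and lower, with Clec4e at 3.59 ± 0.15 and the fungal sugar receptor gene Clec7a at -2.89 ± 0.18. Eicosanoid genes gave 3 and 5 of 15 (4 and 5 adjusted over the list alone, adjusted p = 0.579), and their median (0.03) had the other sign than their mean (-0.21). The prostaglandin E synthase gene Ptges (3.29 ± 0.12) and the cyclooxygenase gene Ptgs2 (1.14 ± 0.14 [larger offset 0.59, no offset 2.13]) rose, and the leukotriene-pathway gene Alox5ap (-2.64 ± 0.12) and the thromboxane synthase gene Tbxas1 (-2.82 ± 0.17) fell. In the inflammasome list, with 3 and 4 of 15 (3 and 4 adjusted over the list alone, adjusted p = 0.783), Casp4 (1.96 ± 0.11) rose and the median (-0.07) lay below 0 while the mean (0.25) lay above it. Oxidative stress, iron and metal response genes gave 3 and 7 of 20 (3 and 7 adjusted over the list alone, adjusted p = 0.143), and the iron exporter gene Slc40a1 (-1.98 ± 0.11) fell. Proteases, inhibitors and matrix genes gave 8 and 4 of 21 (8 and 6 adjusted over the list alone, adjusted p = 0.144), with a median of -0.003 beside a mean of 0.48. Plat (3.36 ± 0.19), Serpinb2 (2.88 ± 0.18) and Mmp13 (2.57 ± 0.20 [probe mean 1.66]) rose, and Timp2 (-2.85 ± 0.13) fell. Chemokine and adhesion receptors gave 4 and 4 of 12 (5 and 5 adjusted over the list alone, adjusted p = 0.659). The counts were 5 and 4 of 16 (6 and 4 adjusted over the list alone, adjusted p = 0.322) for glycolysis. They were 0 and 6 of 25 (0 and 6 adjusted over the list alone, adjusted p = 0.205) for respiratory chain subunits. Cholesterol synthesis gave 5 and 2 of 17 (5 and 3 adjusted over the list alone, adjusted p = 0.57), and its median (-0.03) and mean (0.08) differed in sign. Cell cycle genes gave 4 and 8 of 22 (4 and 8 adjusted over the list alone, adjusted p = 0.21). Apoptosis and survival genes gave 6 and 3 of 20 (8 and 4 adjusted over the list alone, adjusted p = 0.375), and endoplasmic reticulum stress genes 4 and 3 of 20 (4 and 3 adjusted over the list alone, adjusted p = 0.473). For complement the counts were 3 and 1 of 9 (3 and 1 adjusted over the list alone, adjusted p = 0.322), where the median was -0.04 and the mean 0.41. Osteoclast differentiation genes gave 2 and 6 of 14 (2 and 6 adjusted over the list alone, adjusted p = 0.113).

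Among cell type markers, those of dendritic cell identity gave 9 and 3 of 20 (9 and 4 adjusted over the list alone, adjusted p = 0.111). Neutrophil and granulocyte precursor markers gave 2 and 2 of 9 (3 and 3 adjusted over the list alone, adjusted p = 0.425). Fibroblast and stromal markers gave 1 and 5 of 12 (2 and 5 adjusted over the list alone, adjusted p = 0.207), with Acta2 at -2.23 ± 0.23 [probe mean -1.27] and Dcn at 0.84 ± 0.16 [probe mean 0.48]. Mast cell, basophil and eosinophil markers gave 3 and 0 of 9 (3 and 0 adjusted over the list alone, adjusted p = 0.0805), and Hdc, the enzyme that makes histamine, rose 27.2-fold (4.77 ± 0.18). Lymphocyte markers gave 1 and 0 of 10 (1 and 0 adjusted over the list alone, adjusted p = 0.934), with Blnk higher (0.74 ± 0.16), and their median (-0.13) and mean (0.01) differed in sign. Erythroid and megakaryocyte markers gave 1 and 0 of 4 (1 and 0 adjusted over the list alone, adjusted p = 0.817), with a median of -0.001 and a mean of 0.01. Reference genes gave 2 and 4 of 12 (2 and 4 adjusted over the list alone, adjusted p = 0.502), with Tfrc at -1.33 ± 0.12 and Pgk1 at 0.90 ± 0.15 [probe mean 0.60].

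In all, 3454 of 13706 genes (25.2%) changed with Aa, 1543 higher and 1911 lower, and 933 of them by 2-fold or more (453 higher and 480 lower). By 8-fold or more, 49 rose and 19 fell, and 4716 genes had an unadjusted p under 0.05. The arrays of the 2 groups did not overlap in 5223 genes (38.1%, against 10% by chance). The rule for naming genes favours large changes and in part asks for arrays that do not overlap, so the separation of its genes is no further evidence. Of the 148 genes named by rule that passed, 147 had arrays that did not overlap, and the exception was the cholesterol transporter gene Stard4 (0.58 ± 0.20, adjusted p = 0.0457). Its call was lost without Aa 2 (adjusted p = 0.201), Aa 3 (0.0888), Pg 1 (0.0592), Pg 2 (0.0585), Pg 3 (0.0549), Control 1 (0.191) or Control 2 (0.0716), in a range of 0.00822 to 0.201, and its change was 0.38 without Control 1. The values have a floor near 4.2, so a fold from a gene at the floor in either group depends on the offset beneath it, such as those of Il10 (4.4 ± 0.09 SD), Il23a (4.76 ± 0.20) and Hdc (4.69 ± 0.28) in uninfected cells.

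The comparison of Pg-infected with uninfected cells asks the same question for the other bacterium. Lcn2 rose 137-fold (log2 change 7.10 ± 0.20, n = 3 arrays per group, adjusted p = 1.43e-10), Cxcl2 40.3-fold and Cxcl1 36.6-fold. Marco, a scavenger receptor for bacteria, rose 15.9-fold (3.99 ± 0.19), and Fpr2, a receptor for formylated bacterial peptides, rose by 3.74 ± 0.13 on the log2 scale. The platelet and myeloid chemokine Ppbp rose 11.5-fold (3.53 ± 0.18, adjusted p = 1.6e-08). Ccl6 fell by 3.06 ± 0.14, the mannose receptor gene Mrc1 by 3.03 ± 0.20 and the lipid carrier gene Apoe fell by 2.71 ± 0.16.

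Inflammatory mediators rose with Pg as well. Of the pro-inflammatory cytokines, 9 of 14 rose and 0 fell (9 and 0 adjusted over the list alone, adjusted p = 2.52e-12). Among them were Il12a, a subunit of interleukin 12 (3.53 ± 0.16), Il6 (3.44 ± 0.18), Il1b (3.26 ± 0.12) and Tnf (3.02 ± 0.15). Il23a was at 0.09 ± 0.14 (adjusted p = 0.776). For anti-inflammatory and feedback regulators, 9 of 16 rose and 1 fell (9 and 1 adjusted over the list alone, adjusted p = 2.33e-06). Socs3 (2.93 ± 0.15), the signalling inhibitor gene Irak3 (1.83 ± 0.12) and Il10 (1.73 ± 0.23 [larger offset 0.94, no offset 3.39]) were higher and Il10ra (-0.80 ± 0.13) was lower. Chemokines gave 8 increases and 3 decreases among 18 members (10 and 3 adjusted over the list alone, adjusted p = 2.93e-05), with Ccl6, Ccl9 (-1.56 ± 0.12) and Ccl7 (-1.40 ± 0.13) as the decreases. NF-kB components and targets gave 8 increases and 0 decreases among 17 members (8 and 2 adjusted over the list alone, adjusted p = 0.00029), and Nfkbiz was at 2.63 ± 0.13. Maturation genes gave 11 increases and 0 decreases among 22 members (13 and 2 adjusted over the list alone, adjusted p = 1.17e-07). Cd70 (1.5 ± 0.12), Cd86 (1.20 ± 0.12), Cd40 (1.19 ± 0.11) and Cd80 (0.87 ± 0.12) rose, while Ccr7 was at 0.04 ± 0.16 (adjusted p = 0.921).

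Antimicrobial effectors were higher with Pg. Of antimicrobial and oxidant effectors, 10 of 19 rose and 0 fell (10 and 0 adjusted over the list alone, adjusted p = 3.6e-12), including Saa3 (3.66 ± 0.11), Slpi (3.36 ± 0.14) and Slc7a2 (3.12 ± 0.14 [probe mean 1.46]). Nos2 was at -0.04 ± 0.13 (adjusted p = 0.923). For pattern recognition receptors and adaptors, 10 of 29 rose and 5 fell (10 and 5 adjusted over the list alone, adjusted p = 0.00196), with adjusted p = 0.251 with an estimated correlation. Clec4e (3.22 ± 0.15), Trem3 (2.91 ± 0.24 [larger offset 1.93]) and Cd14 (1.90 ± 0.14) rose with Marco, and Clec7a (-0.99 ± 0.18), Tlr4 (-0.80 ± 0.15), Tlr8, Tlr7 and Msr1 fell. Without Pg 3 the median of this list went from 0.17 to 0.09. In the inflammasome list, 4 of 15 rose and 2 fell (5 and 3 adjusted over the list alone, adjusted p = 0.0282), with adjusted p = 0.109 with an estimated correlation. Il1b, Mefv (1.86 ± 0.12), Casp4 (0.86 ± 0.11) and Panx1 (0.58 ± 0.12) rose, and Txnip (-1.19 ± 0.15) and Pycard (-0.61 ± 0.11) fell. That call ended without Control 3 (adjusted p = 0.0511, range 0.0159 to 0.0511), and without Control 1 its median went from 0.16 to 0.28.

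Oxidative stress, iron and metal response genes rose with Pg: 10 of 20 rose and 1 fell (12 and 1 adjusted over the list alone, adjusted p = 4.8e-08). The mitochondrial superoxide dismutase gene Sod2 (1.56 ± 0.13), the quinone reductase gene Nqo1 (1.53 ± 0.16 [probe mean 0.68]) and the haem oxygenase gene Hmox1 (1.23 ± 0.15) rose, and Slc40a1 (-1.01 ± 0.11) fell. Hypoxia response genes gave 6 increases and 0 decreases among 15 members (8 and 0 adjusted over the list alone, adjusted p = 7.82e-05), with adjusted p = 0.17 with an estimated correlation. Ankrd37 (3.25 ± 0.25) and Hif1a (0.99 ± 0.14) rose. Interferon-gamma-inducible GTPases and effectors gave 7 increases and 3 decreases among 20 members (7 and 3 adjusted over the list alone, adjusted p = 0.0359), with adjusted p = 0.173 with an estimated correlation. The nucleoside enzyme gene Upp1 (1.99 ± 0.16 [probe mean 1.28]), Gbp2 (1.79 ± 0.15 [probe mean 1.13]) and Gbp5 (1.71 ± 0.22 [probe mean 0.91, larger offset 1.01, no offset 2.79]) rose, and Fcgr4 (-1.53 ± 0.12), Fcgr1 (-0.99 ± 0.16) and Ifngr2 (-0.43 ± 0.11) fell. The call ended without Pg 1 (adjusted p = 0.0628) and without Control 1 (adjusted p = 0.102), in a range of 0.0171 to 0.102. Its median of 0.06 became 0.00 without Control 1, 0.10 without Control 3 and 0.13 without Pg 2.

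Lipid and lysosomal genes were lower with Pg. For lipid uptake, storage and efflux, 0 of 19 rose and 8 fell (0 and 11 adjusted over the list alone, adjusted p = 1.89e-06). Apoe, Pparg (-2.46 ± 0.17) and the lipid droplet coat gene Plin2 (-1.37 ± 0.19) were lower. In the lysosome and phagosome list, 0 of 22 rose and 9 fell (0 and 9 adjusted over the list alone, adjusted p = 9.31e-06). Ctsl (-1.15 ± 0.14 [larger offset -0.57, no offset -2.40]) and Grn (-0.99 ± 0.11) were lower. Of M2-associated markers, 0 of 12 rose and 4 fell (0 and 4 adjusted over the list alone, adjusted p = 0.000917), namely Mrc1, Pparg, Stab1 (-0.61 ± 0.13) and Mgl2 (-0.77 ± 0.22 [larger offset -0.47], adjusted p = 0.0357). The call of Mgl2 ended without Pg 2 (adjusted p = 0.145), Pg 3 (0.0705), Control 2 (0.108) or Control 3 (0.112), in a range of 0.00608 to 0.145. Osteoclast differentiation genes, which include receptors and adaptors of other myeloid cells, gave 1 increase and 4 decreases among 14 members (1 and 4 adjusted over the list alone, adjusted p = 0.0366), with adjusted p = 0.126 with an estimated correlation. Trem2 (-1.76 ± 0.19), Fos (-1.04 ± 0.16), Tyrobp (-0.81 ± 0.12) and Nfatc1 (-0.45 ± 0.13) fell. The acid phosphatase gene Acp5 (0.85 ± 0.19 [larger offset 0.48, no offset 1.34]) rose, a call lost without Pg 2 (adjusted p = 0.0502, range 0.00148 to 0.0502). The call of the list ended without Pg 2 (adjusted p = 0.0537), without Control 3 (adjusted p = 0.0531) and with no offset, in a range of 0.0294 to 0.0586, and the median of -0.12 was -0.08 without Pg 1. Macrophage and monocyte markers moved with these lists: 2 of 12 rose and 5 fell (2 and 9 adjusted over the list alone, adjusted p = 0.000791), with adjusted p = 0.212 with an estimated correlation. C1qc (-2.87 ± 0.13), C1qb (-2.55 ± 0.13), C1qa (-1.63 ± 0.14), Mertk and Fcgr1 fell, and Adgre1 (2.35 ± 0.14) and Cd14 rose.

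Neutrophil and granulocyte precursor markers gave 3 increases and 0 decreases among 9 members (3 and 2 adjusted over the list alone, adjusted p = 0.00876), with adjusted p = 0.0791 with an estimated correlation. Lcn2, the calprotectin subunit gene S100a8 (3.04 ± 0.13) and the antimicrobial peptide gene Camp (0.86 ± 0.19 [larger offset 0.40, no offset 2.09]) rose, and without Pg 2 the median went from 0.18 to 0.10. Fibroblast and stromal markers gave 0 increases and 4 decreases among 12 members (0 and 5 adjusted over the list alone, adjusted p = 0.00876), with adjusted p = 0.174 with an estimated correlation. Bgn (-1.21 ± 0.15), Sparc (-0.99 ± 0.15 [probe mean -0.57]) and Dcn (-0.86 ± 0.16 [probe mean -0.47]) fell. Acta2 (-0.84 ± 0.23 [probe mean -0.52], adjusted p = 0.0302) lost its call without Pg 1 (adjusted p = 0.128), Pg 2 (0.0873) or any 1 uninfected array (from 0.053 for Control 1 to 0.102 for Control 3), in a range of 0.00302 to 0.134. Mast cell, basophil and eosinophil markers gave 0 and 0 of 9 (1 and 0 adjusted over the list alone, adjusted p = 0.087) higher and lower, with Hdc at 0.27 ± 0.18. Erythroid and megakaryocyte markers gave 0 and 0 of 4 (0 and 0 adjusted over the list alone, adjusted p = 0.405). Lymphocyte markers gave 0 and 0 of 10 (0 and 0 adjusted over the list alone, adjusted p = 0.322). Dendritic cell identity markers gave 3 and 2 of 20 (3 and 3 adjusted over the list alone, adjusted p = 0.958). Their median (-0.05) and mean (-0.04) lay below 0 while the test pointed up. Reference genes gave 1 and 0 of 12 (1 and 0 adjusted over the list alone, adjusted p = 0.322).

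Lists without a shift past the threshold with Pg include type I interferon genes, with 5 and 2 of 26 (5 and 3 adjusted over the list alone, adjusted p = 0.0669) higher and lower. Isg15 (1.94 ± 0.16), Oasl1 (1.37 ± 0.19 [probe mean 0.79]) and Trim30a (0.97 ± 0.19) rose, and the list was called without Pg 2 (adjusted p = 0.0177) or Control 2 (adjusted p = 0.0101, range 0.0101 to 0.228). MHC class I presentation genes gave 2 and 0 of 19 (2 and 0 adjusted over the list alone, adjusted p = 0.15). For MHC class II the counts were 0 and 2 of 14 (0 and 3 adjusted over the list alone, adjusted p = 0.194). The peptide-loading gene H2-DMa (-0.70 ± 0.11) and Lgmn (-1.15 ± 0.12) fell. For eicosanoid genes the counts were 4 and 2 of 15 (4 and 2 adjusted over the list alone, adjusted p = 0.111). Ptges (1.43 ± 0.12 [larger offset 0.77, no offset 2.57]) and the leukotriene receptor gene Ltb4r1 (1.20 ± 0.17) rose, and the list was called without Pg 3 (adjusted p = 0.0266, range 0.0266 to 0.267). Glycolysis genes gave 0 and 1 of 16 (0 and 1 adjusted over the list alone, adjusted p = 0.783), and Hk3 (-1.52 ± 0.15) fell. Tricarboxylic acid cycle genes gave 0 and 2 of 18 (0 and 2 adjusted over the list alone, adjusted p = 0.639). Respiratory chain subunits gave 0 and 0 of 25 (0 and 0 adjusted over the list alone, adjusted p = 0.57). Cholesterol synthesis gave 3 and 2 of 17 (3 and 2 adjusted over the list alone, adjusted p = 0.338). In the cell cycle list, with 2 and 1 of 22 (3 and 5 adjusted over the list alone, adjusted p = 0.338), Tyms (1.74 ± 0.13 [probe mean 0.56]) rose. Apoptosis and survival genes gave 1 and 1 of 20 (1 and 2 adjusted over the list alone, adjusted p = 0.837). Endoplasmic reticulum stress genes gave 0 and 1 of 20 (0 and 1 adjusted over the list alone, adjusted p = 0.675). Proteases, inhibitors and matrix genes gave 6 and 4 of 21 (9 and 5 adjusted over the list alone, adjusted p = 0.322). Plat (2.13 ± 0.19) was higher and Timp2 (-2.15 ± 0.13) was lower. Chemokine and adhesion receptors gave 2 and 2 of 12 (3 and 2 adjusted over the list alone, adjusted p = 0.934), with a median of 0.11 and a mean of -0.08. Complement genes gave 2 and 1 of 9 (2 and 2 adjusted over the list alone, adjusted p = 0.405), with a median of -0.01 and a mean of 0.25. The complement factor gene Cfb rose (2.57 ± 0.13).

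In all, 1457 genes (10.6%) changed with Pg, 681 higher and 776 lower, and 347 of them by 2-fold or more (187 higher and 160 lower). By 8-fold or more, 22 rose and 2 fell (Ccl6 and Mrc1), and 3085 had an unadjusted p under 0.05. Arrays did not overlap in 3672 genes (26.8%, against 10% by chance). Among the 116 genes named by rule that passed, a choice that favours separated arrays, Ifit3 alone had overlapping arrays.

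**Figure D2:**
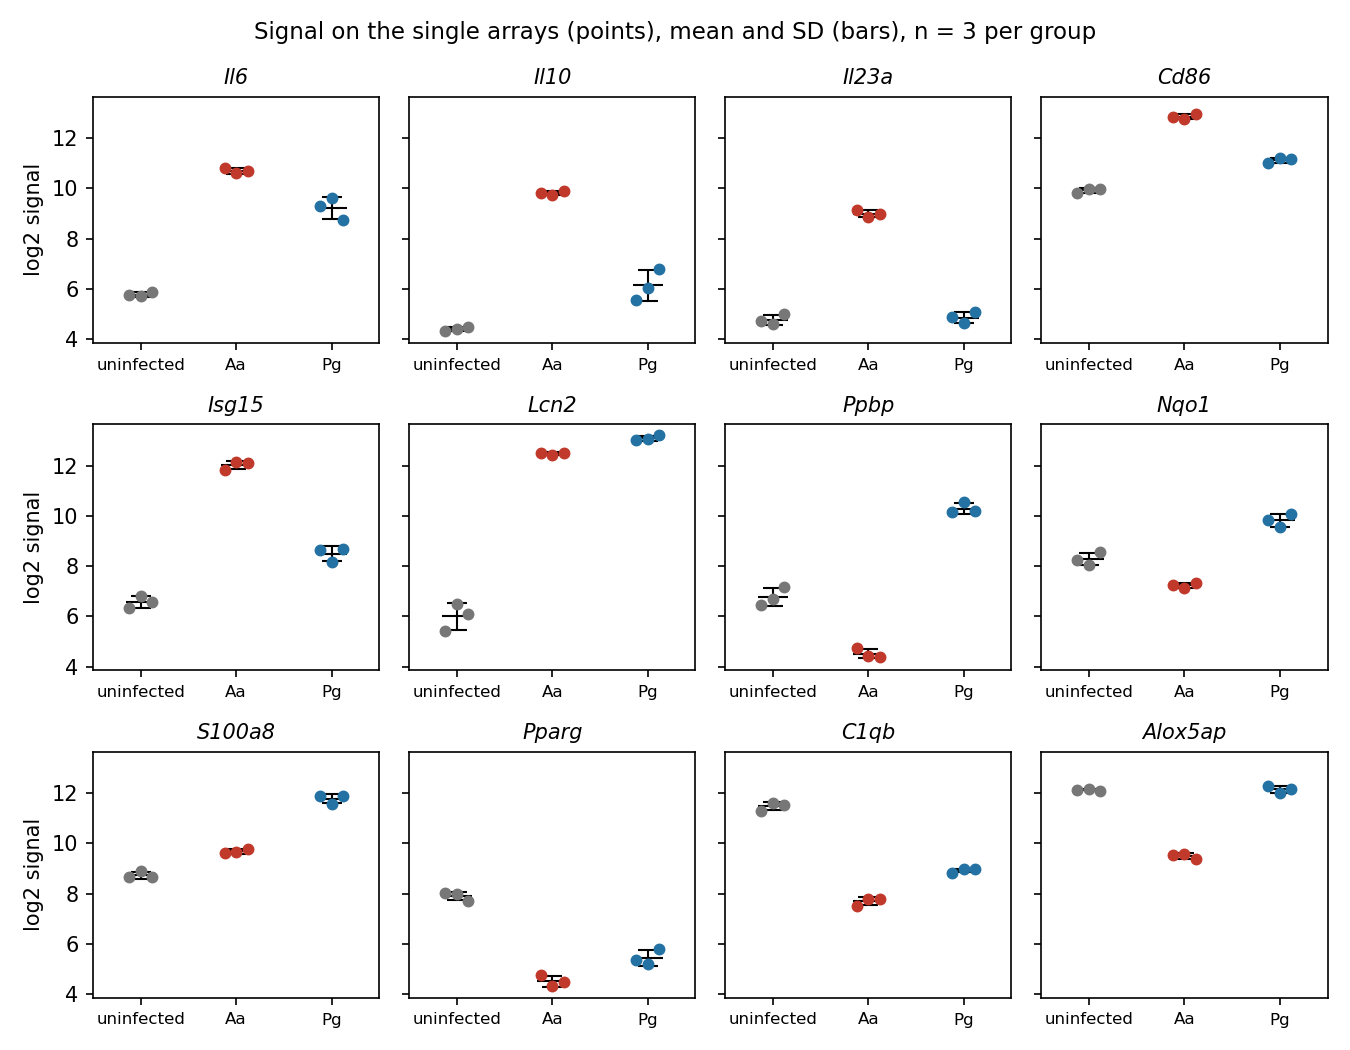
Log2 signal of 12 genes on each array, with the group on the x axis. Points are single arrays and bars give the mean and SD (n = 3), and Il6 and Lcn2 are higher in both infections, Ppbp and Nqo1 move in opposite directions, and Alox5ap is lower with Aa (9.50 ± 0.12 SD) than with Pg (12.16 ± 0.13).

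The direct comparison of the infections tests the difference between the responses to the bacteria. Hdc was 22.6-fold higher with Aa than with Pg (log2 difference 4.50 ± 0.18, n = 3 arrays per group, adjusted p = 3.62e-09), Il23a 17.6-fold, Inhba 14.6-fold, Il10 12.8-fold and Isg15 11.5-fold. Ppbp was lower with Aa by a log2 difference of -5.77 ± 0.18 (adjusted p = 7.11e-10), Ch25h by -2.99 ± 0.11 and the epoxide hydrolase gene Ephx1 by -2.86 ± 0.11. The signal of Ppbp with Aa (4.52 ± 0.19 SD) lay near the floor, so its difference depends on the offset, at -4.50 with a larger offset and -7.55 with no offset. Alox5ap (-2.66 ± 0.12) and Nqo1 (-2.58 ± 0.16 [probe mean -1.24]) were also lower with Aa.

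Cytokine, maturation and interferon genes were higher with Aa. For pro-inflammatory cytokines, 13 of 14 were higher and 0 lower (13 and 0 adjusted over the list alone, adjusted p = 5.6e-17). Ebi3 (1.97 ± 0.11) and Il6 (1.49 ± 0.18) were higher beside Il23a, whose difference averaged over its probes was 2.40. For feedback regulators, 8 of 16 were higher and 2 lower (10 and 3 adjusted over the list alone, adjusted p = 7.74e-06). Il1r2 (2.15 ± 0.13) and Cish (1.90 ± 0.12) were higher and Tgfbi (-1.01 ± 0.13) and Zfp36 (-0.55 ± 0.12) were lower. For maturation genes, 13 of 22 were higher and 1 lower (17 and 1 adjusted over the list alone, adjusted p = 3.01e-13). Slamf1 (2.30 ± 0.12 [larger offset 1.40, no offset 3.65]), Tnfsf9 (2.16 ± 0.15 [larger offset 1.44]) and Cd80 (2.02 ± 0.12) were higher and Relb (-0.45 ± 0.11) was lower. For NF-kB components and targets, 8 of 17 were higher and 2 lower (8 and 4 adjusted over the list alone, adjusted p = 0.00135), with adjusted p = 0.0693 with an estimated correlation and Tnfaip3 at 1.71 ± 0.14. Type I interferon genes gave 18 of 26 higher and 1 lower (20 and 1 adjusted over the list alone, adjusted p = 4.73e-18). Ifit3 (3.41 ± 0.21), Rsad2 (2.78 ± 0.16) and Oasl2 (2.17 ± 0.28) were higher and Mx1 (-0.62 ± 0.19) was lower. Interferon-gamma-inducible genes gave 11 of 20 higher and 0 lower (11 and 2 adjusted over the list alone, adjusted p = 8.92e-07). Gbp5 (2.33 ± 0.22 [probe mean 1.40]), Ifi47 (2.17 ± 0.14) and Igtp (1.59 ± 0.18) were higher. MHC class I genes gave 8 of 19 higher and 1 lower (10 and 2 adjusted over the list alone, adjusted p = 0.00086). Tap1 (0.94 ± 0.14) and Tap2 (0.86 ± 0.12) were higher and Calr (-0.55 ± 0.12) was lower. MHC class II genes gave 7 of 14 higher and 2 lower (10 and 2 adjusted over the list alone, adjusted p = 0.000101). H2-Ob (1.49 ± 0.22 [larger offset 0.83, no offset 2.61]), Ciita (1.17 ± 0.13) and H2-DMb1 (1.17 ± 0.11) were higher and Ifi30 (-0.90 ± 0.12) and Marchf1 (-0.73 ± 0.17) were lower. Dendritic cell identity markers moved with these lists, at 7 of 20 higher and 1 lower (7 and 1 adjusted over the list alone, adjusted p = 0.0291), with adjusted p = 0.109 with an estimated correlation. Tcf4 (1.26 ± 0.11 [probe mean 0.57]) and Irf4 (1.13 ± 0.12) were higher. That call ended without Aa 3 (adjusted p = 0.0629, range 0.0108 to 0.0629), and the median of 0.05 was 0.11 without Aa 1, 0.10 without Pg 3 and 0.03 without Pg 2.

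Hypoxia response genes were higher with Aa as well: 7 of 15 were higher and 1 lower (8 and 2 adjusted over the list alone, adjusted p = 0.000541), with adjusted p = 0.201 with an estimated correlation. Ndrg1 (1.93 ± 0.14) and the growth factor gene Vegfa (1.31 ± 0.13) were higher and Ankrd37 (-0.85 ± 0.25) lower, and without Aa 2 the median went from 0.60 to 0.36.

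Antioxidant genes were lower with Aa than with Pg. Oxidative stress, iron and metal response genes gave 0 of 20 higher and 9 lower (1 and 13 adjusted over the list alone, adjusted p = 8.38e-10). The glutathione synthesis gene Gclm (-2.43 ± 0.14), Tfrc (-1.84 ± 0.12) and Blvrb (-1.33 ± 0.12) were lower beside Nqo1. Pattern recognition receptors and adaptors gave 1 of 29 higher and 12 lower (3 and 14 adjusted over the list alone, adjusted p = 7.82e-05), with adjusted p = 0.174 with an estimated correlation. Tlr13 (-2.01 ± 0.16), Clec7a (-1.89 ± 0.18) and Marco (-1.74 ± 0.19) were lower and Ly96 (0.48 ± 0.12) higher. For eicosanoid genes, 2 of 15 were higher and 5 lower (2 and 5 adjusted over the list alone, adjusted p = 0.0417), with adjusted p = 0.277 with an estimated correlation. Tbxas1 (-2.06 ± 0.17) was lower and Ptges (1.86 ± 0.12) higher. The eicosanoid call ended without Aa 1 (adjusted p = 0.0587), Aa 2 (adjusted p = 0.0559), Pg 1 (adjusted p = 0.0742) or Pg 2 (adjusted p = 0.154), in a range of 0.00626 to 0.154. The median of -0.21 was -0.14 without Pg 1. Lipid genes gave 1 of 19 higher and 5 lower (1 and 5 adjusted over the list alone, adjusted p = 0.00708), with adjusted p = 0.0639 with an estimated correlation. Lipa (-2.26 ± 0.12) and Lpl (-1.60 ± 0.14 [probe mean -0.88]) were lower and Pltp (1.20 ± 0.14 [larger offset 0.73]) higher. Lysosome and phagosome genes gave 0 of 22 higher and 6 lower (1 and 8 adjusted over the list alone, adjusted p = 0.0111), with adjusted p = 0.126 with an estimated correlation, and the membrane protein gene Lamp1 (-0.76 ± 0.11) was lower. The call of the lysosome list ended without Pg 1 (adjusted p = 0.0587, range 0.00162 to 0.0587). Tricarboxylic acid cycle genes gave 1 of 18 higher and 6 lower (1 and 9 adjusted over the list alone, adjusted p = 0.0125), with adjusted p = 0.251 with an estimated correlation. Idh1 (-1.42 ± 0.12) and Idh2 (-0.78 ± 0.14) were lower and Mdh1 (0.63 ± 0.13) higher. Macrophage markers moved with these lists, at 0 of 12 higher and 7 lower (1 and 8 adjusted over the list alone, adjusted p = 8.69e-05), with adjusted p = 0.173 with an estimated correlation. Adgre1 (-1.65 ± 0.14) and the growth factor receptor gene Csf1r (-1.35 ± 0.15) were lower. Neutrophil markers did too, at 0 of 9 higher and 1 lower (0 and 3 adjusted over the list alone, adjusted p = 0.0111), with adjusted p = 0.0867 with an estimated correlation. S100a8 (-2.09 ± 0.13) was the member that passed, and without Pg 2 the median went from -0.28 to -0.17.

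Between the infections, chemokines gave 7 and 4 of 18 (9 and 4 adjusted over the list alone, adjusted p = 0.13) higher and lower with Aa. Ccl4 (2.79 ± 0.15) was higher and Pf4 (-1.70 ± 0.13) lower, and the list's median (0.28) and mean (-0.03) differed in sign. Antimicrobial effectors gave 4 and 5 of 19 (5 and 6 adjusted over the list alone, adjusted p = 0.563). Nos2 (1.29 ± 0.13 [probe mean 0.58, larger offset 0.67, no offset 2.51]) was higher and the arginine synthesis gene Ass1 (-1.52 ± 0.11) was lower. Glycolysis genes gave 4 and 1 of 16 (4 and 1 adjusted over the list alone, adjusted p = 0.0586). The list was called without Aa 1 (adjusted p = 0.0451), without Aa 3 (adjusted p = 0.00369) and without Pg 3 (adjusted p = 0.0495). It was farthest from a call without Aa 2 (adjusted p = 0.323), in a range of 0.00369 to 0.323. The lactate dehydrogenase gene Ldha was higher with Aa (0.82 ± 0.16). Endoplasmic reticulum stress genes gave 5 and 2 of 20 (5 and 3 adjusted over the list alone, adjusted p = 0.322), with Chac1 (1.87 ± 0.13) and Asns (1.34 ± 0.13) higher, a median of -0.04 and a mean of 0.17. Proteases and matrix genes gave 6 and 5 of 21 (6 and 6 adjusted over the list alone, adjusted p = 0.148). Serpinb2 (3.03 ± 0.18) and Mmp13 (2.94 ± 0.20 [probe mean 1.82]) were higher and Mmp9 (-1.42 ± 0.14) was lower. Inflammasome genes gave 2 and 4 of 15 (2 and 4 adjusted over the list alone, adjusted p = 0.353). Chemokine and adhesion receptors gave 4 and 2 of 12 (5 and 5 adjusted over the list alone, adjusted p = 0.454), and complement 2 and 1 of 9 (2 and 1 adjusted over the list alone, adjusted p = 0.322). Apoptosis and survival genes gave 2 and 2 of 20 (2 and 2 adjusted over the list alone, adjusted p = 0.346), with the death receptor gene Fas (-1.62 ± 0.12 [probe mean -1.05]) lower. Cell cycle genes gave 1 and 3 of 22 (1 and 4 adjusted over the list alone, adjusted p = 0.322). Respiratory chain subunits gave 0 and 2 of 25 (0 and 1 adjusted over the list alone, adjusted p = 0.264). Cholesterol synthesis gave 2 and 2 of 17 (2 and 2 adjusted over the list alone, adjusted p = 0.904), and osteoclast differentiation 1 and 3 of 14 (1 and 3 adjusted over the list alone, adjusted p = 0.322). M2-associated markers gave 1 and 2 of 12 (1 and 2 adjusted over the list alone, adjusted p = 0.766), with a median of 0.04 and a mean of -0.05. Fibroblast markers gave 1 and 1 of 12 (1 and 1 adjusted over the list alone, adjusted p = 0.743), with a median of -0.02, a mean of 0.05 and Dcn higher (1.70 ± 0.16 [probe mean 0.95]). Mast cell markers gave 2 and 0 of 9 (2 and 0 adjusted over the list alone, adjusted p = 0.405), and lymphocyte markers 1 and 0 of 10 (1 and 0 adjusted over the list alone, adjusted p = 0.346). The counts were 1 and 0 of 4 (1 and 0 adjusted over the list alone, adjusted p = 0.309) for erythroid and megakaryocyte markers and 2 and 4 of 12 (2 and 4 adjusted over the list alone, adjusted p = 0.151) for reference genes.

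In all, 1883 genes (13.7%) differed between the infections, 828 higher and 1055 lower with Aa, 445 of them by 2-fold or more (218 higher and 227 lower). By 8-fold or more, 8 were higher and Ppbp was lower, and 3306 had an unadjusted p under 0.05. Arrays did not overlap in 4002 genes (29.2%, against 10% by chance), nor in any of the 141 genes named by rule that passed, a choice that favours separated arrays.

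**Figure D3:**
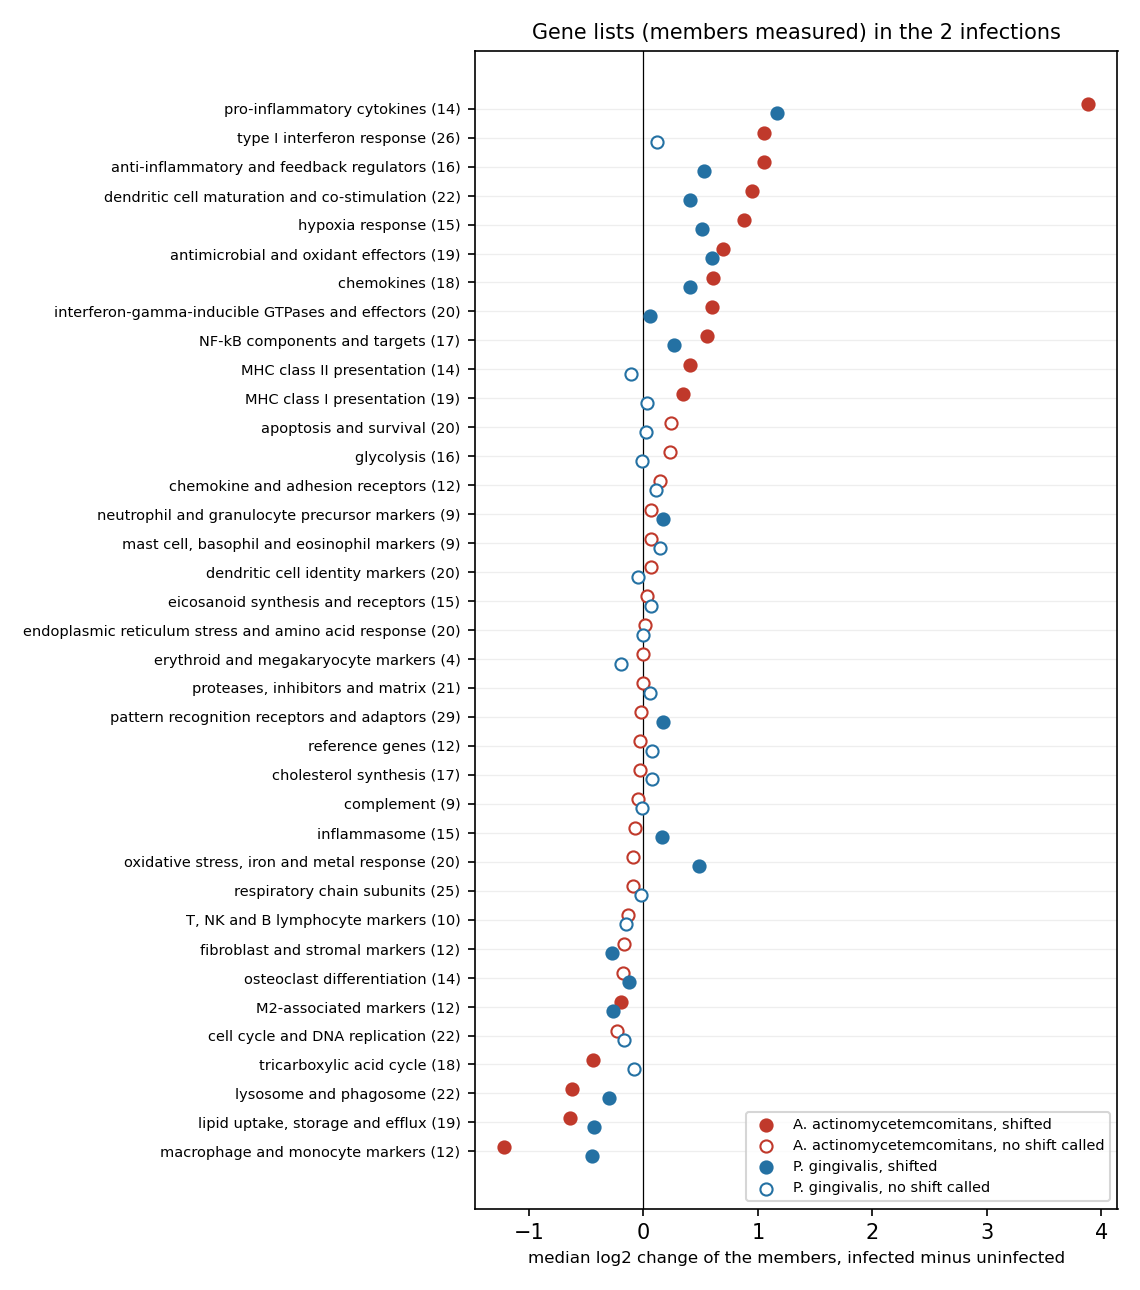
Median log2 change of each gene list in the 2 infections against uninfected cells, with lists on the y axis. Filled points mark lists that camera called with the preset correlation and open points the others. Cytokines lie to the right of 0 in both infections (medians 3.89 with Aa and 1.17 with Pg, or 1.94 and 0.44 without the filter on dim probes).

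Set side by side, the responses to the 2 bacteria shared many genes and differed in size. Of the 1457 genes changed with Pg, 78.7% were also changed with Aa in the same direction. Both infections raised 494 genes, including Lcn2, Cxcl1, Il6 and Clec4e, and lowered 653, including Ccl6, C1qc, Mrc1 and Apoe. Independent lists of these sizes would share 76.7 and 108.2, and unchanged groups simulated against the same uninfected arrays shared 0, a count that says little because unchanged groups give few calls. Log2 changes correlated across genes at r = 0.73 (Spearman rho 0.66), against 0.50 and 0.48 in the simulation. The simulated values are those of unchanged groups, so they are not the part of 0.73 owed to the shared arrays. The covariance of the changes was 0.17 against 0.011, a difference of 0.159. From that difference, and with the squared standard errors taken off the variances of the changes, r was 0.76. With 3 uninfected arrays the controls cannot be split into parts of 2 arrays, so part of the excess of shared calls may come from the shared controls, while the covariance difference is taken against groups that share them. Of the 1147 genes changed the same way, 492 differed between the infections, 456 with a larger change with Aa, such as Il10 and Isg15, and 36 with a larger change with Pg, such as Marco and S100a8. A further 2256 genes passed with Aa alone, of which 1024 differed between the infections, and 259 with Pg alone, of which 111 did.

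Opposite directions were found for 51 genes, 36 lower with Aa and higher with Pg and 15 the reverse. Independent lists would give 182.3 and the simulation gave 0. Neither is a value for no change, since unchanged groups give few calls and shared uninfected arrays push changes to the same sign (66.7% of genes in the simulation, 74.3% here). Ppbp fell with Aa (log2 change -2.24 ± 0.18 [larger offset -1.33, no offset -3.80], adjusted p = 4.08e-07) and rose with Pg (3.53 ± 0.18), from 6.76 ± 0.36 (SD) in uninfected cells to 4.52 ± 0.19 and 10.29 ± 0.22. The glutathione transferase gene Gsta3 (-0.90 ± 0.13 [probe mean -0.42] with Aa and 1.87 ± 0.13 [probe mean 1.08] with Pg), Nqo1 (-1.05 ± 0.16 [probe mean -0.56] and 1.53 ± 0.16 [probe mean 0.68]) and Gclm (-1.69 ± 0.14 and 0.74 ± 0.14) went the same opposite ways, all genes of antioxidant or detoxifying enzymes. So did the carbonyl reductase gene Cbr3 (-2.07 ± 0.12 and 0.47 ± 0.12), Nnmt (-1.60 ± 0.14 [probe mean -0.98, larger offset -0.91, no offset -2.69] and 0.72 ± 0.14 [probe mean 0.40]), Slc6a13 (-0.54 ± 0.14 and 1.55 ± 0.14), Akr1b8 (-0.54 ± 0.16 and 1.55 ± 0.16) and Nxpe4 (-1.26 ± 0.17 [larger offset -0.66, no offset -2.42] and 0.83 ± 0.17). Ifit3 rose with Aa (2.66 ± 0.21) and was lower with Pg (-0.75 ± 0.21 [probe mean -0.44, larger offset -0.48], adjusted p = 0.0399, range over the other settings 0.00351 to 0.156).

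The count of 51 fell to 24 without Control 2, 29 without Control 3, 32 without Control 1 and 32 without Pg 1. Ifit3 lost its call with Pg in 13 of 20 other settings. Among them were those without Pg 2 (adjusted p = 0.142), Pg 3 (0.11), Control 2 (0.156), Control 3 (0.102) or Aa 1 (0.0526). No offset (0.11) and a larger offset (0.0523) ended this call too. The Pg call of Cbr3 was lost without Pg 1 (adjusted p = 0.0778), Control 2 (0.0827) or Control 3 (0.0528) and with no offset (0.0573, range 0.00103 to 0.0827). The Aa call of Akr1b8 was lost without Aa 1 (adjusted p = 0.0578), Aa 2 (0.113), Control 1 (0.0828) or Control 2 (0.0614) and with no offset (0.0654, range 0.00161 to 0.113). The Pg call of Nnmt was lost with its probes averaged (adjusted p = 0.0751) and with no offset (0.0691, range 0.00133 to 0.0751), and that of Nxpe4 with no offset (0.058, range 0.000743 to 0.058). Slc6a13 lost its Aa call without Aa 2 (0.0642) or Control 1 (0.0551, range 0.000461 to 0.0642).

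**Figure D4:**
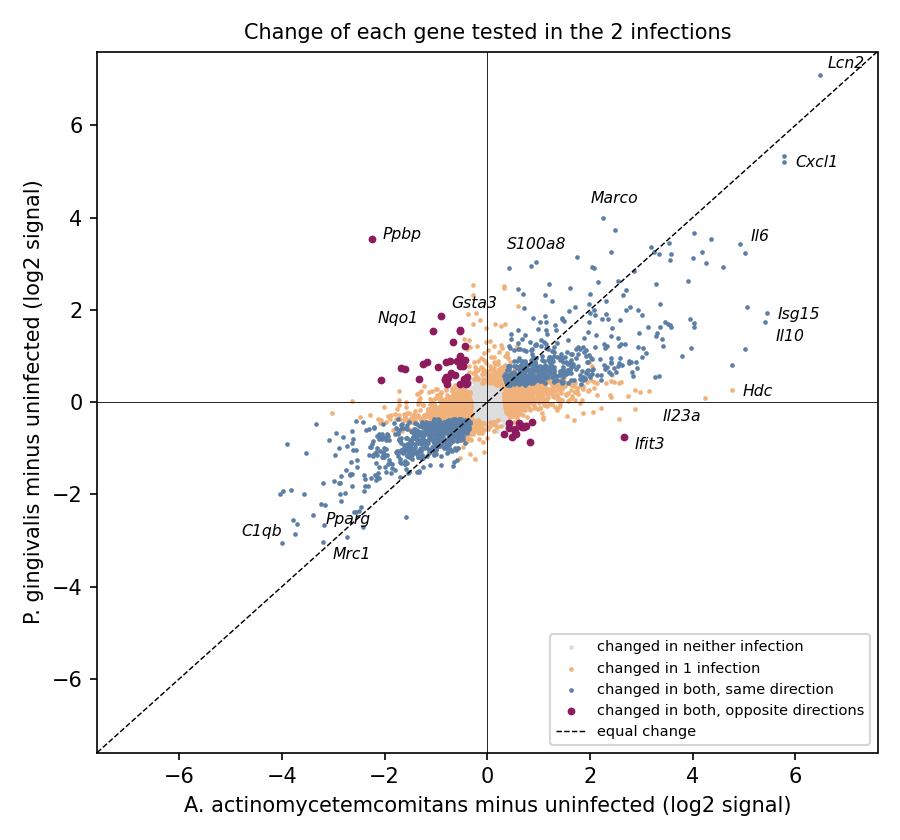
Log2 change of each gene with Aa (x axis) and with Pg (y axis) against the same uninfected arrays. Blue points are the 1147 genes changed in the same direction and purple points the 51 changed in opposite directions. Orange points are genes changed in a single infection and grey points genes changed in neither. The dashed line marks equal changes, and Ppbp lies farthest from it.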

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

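The list of further NRF2 targets, the list of platelet genes and the tests on them were written after the main results were seen but before their own values, and the test of the macrophage share was chosen after its result was seen.

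The log2 difference between the infections, tested in the direct contrast of Aa and Pg, singled out 10 genes that changed in opposite directions against uninfected cells. Lower with Aa than with Pg were Ppbp (-5.77) and the antioxidant and detoxifying genes Gsta3 (-2.77 [probe mean -1.50]), Nqo1 (-2.58 [probe mean -1.24]), Cbr3 (-2.54), Gclm (-2.43) and Akr1b8 (-2.09). So were the methyltransferase gene Nnmt (-2.33 [probe mean -1.38, larger offset -1.45, no offset -3.55]), the transporter gene Slc6a13 (-2.09) and Nxpe4 (-2.09 [larger offset -1.22, no offset -3.49]). Ifit3 was higher with Aa (3.41). Signals of Ppbp with Aa lay near the floor, and its difference was -4.50 with a larger offset and -7.55 with no offset. Lists whose tests pointed in opposite directions in the infections, with a call against uninfected cells in at least 1, and whose difference passed were MHC class II presentation (median difference 0.38), pattern recognition receptors and adaptors (-0.27) and oxidative stress, iron and metal response (-0.38). In none of them was the other infection called by camera. Adjusted p was 0.194 for MHC class II with Pg, and 0.837 for pattern recognition and 0.143 for oxidative stress with Aa. With an estimated correlation the difference of the pattern recognition list had adjusted p = 0.174. So tested, the calls against uninfected cells of MHC class II with Aa (0.109) and pattern recognition with Pg (0.251) were lost too.

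With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For Aa against uninfected cells 1 split, the real one, gave as many genes (3454, highest other 0), as did 1 for Pg against uninfected cells (1457, highest other 0) and 1 for Aa against Pg (1883, highest other 0).

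The rise of Ppbp with Pg was weighed first. Without any 1 array its log2 change was at least 3.38, which argues against 1 array as its cause. RNA of platelets or megakaryocytes in the Pg arrays may contribute and cannot be told apart from a change in the cells: the median change of the 9 measured platelet genes was 0.20 (SD over members 0.64), while 3 of them rose, namely Pf4 (1.34 ± 0.13, adjusted p = 6.33e-06), Gp6 (1.58 ± 0.19) and Alox12 (0.72 ± 0.13). Pf4 stood at 9.75 in uninfected cells, whereas Gp6 (4.52) and Alox12 (4.69) lay near the floor. Gp6 also rose with Aa (0.99, adjusted p = 0.00123), where Ppbp fell. No step that removes platelets is given in the sources used here. Regulation of Ppbp by the bacteria in the cells themselves stays open and was not tested.

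The fall of macrophage and monocyte markers in both infections was weighed next. The list's median change with Aa stayed at -1.18 or lower with centred arrays and with cyclic loess. The quantiles of the arrays were already nearly identical, and centring moved the median change of all genes with Aa only from -0.011 to 0.025. These steps could hardly move the list, so they cannot decide whether scaling of the arrays contributed. A smaller share of macrophages would lower all 12 markers alike only if they were confined to these cells and their expression there was unchanged. With Pg the most raised and most lowered markers, Adgre1 (2.35 ± 0.14) and C1qc (-2.87 ± 0.13), lay 5.22 apart. In each infection 2 markers rose by more than 3 standard errors, which argues against a smaller share as the whole cause. Whether it contributed to the markers that fell cannot be decided, since whole cultures were measured and that condition was not tested. A candidate explanation is a change of the markers' expression within the cells, which these arrays of whole cultures did not test, and the list's call ended with an estimated correlation (adjusted p = 0.169 for Aa and 0.212 for Pg).

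The oxidative stress list, higher with Pg than with Aa, was weighed last. Its median difference stayed at -0.33 or lower with centred arrays and with cyclic loess. These steps could hardly move it either, so they do not decide whether scaling contributed. Without its 4 most different members the remaining 16 had adjusted p = 5.07e-05 by camera, which argues against a few genes as the whole cause. The list of 25 further NRF2 targets, 22 of them measured, was lower with Aa than with Pg (camera p = 2.53e-05, and 0.00432 with an estimated correlation), with 8 lower and 0 higher, among them Mgst1, Slc48a1, Osgin1 and Gss. Against uninfected cells 7 of the 22 rose and 0 fell with Pg. With Aa 4 rose, namely Txn1 (1.18), Abcc4 (0.83), Esd (0.67) and Gstm1 (0.44), and 4 fell, namely Slc48a1 (-1.31), Mgst1 (-1.24), Taldo1 (-0.93) and Tkt (-0.54). The median change of the 22 was small, at 0.10 with Pg and -0.14 with Aa. A candidate explanation is a difference in the activity of NRF2, a regulator of antioxidant genes, which is a hypothesis found and tested on the same data.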

How the results depend on the processing

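A larger offset, no offset, centred arrays and cyclic loess were tests added after seeing the data, and the other settings were chosen before. Of 425 calls of genes named by a fixed rule 370 passed in every setting that held the gene, since the strict filter on dim probes dropped some. Of 52 list calls 44 passed in every setting run for lists, and 0 of the gene and list calls reversed direction. Lists were not run with the strict filter, averaged probes, trended robust moderation, array weights or the fit to the 2 groups compared. Other genes were not followed through the settings, and small medians of some lists without a call did change sign. The estimated correlation is counted apart: it ended 25 list calls and added 0, while fry ended 0 and added 29.

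With every probe tested by itself, 5395 probes changed with Aa (2587 higher, 1419 by 2-fold or more) and 1246 were higher with Aa than with Pg, since more features were tested than genes. With a larger offset the genes changed 2-fold numbered 620 for Aa and 226 for Pg, and with no offset 1407 for Aa, since an offset shrinks folds of dim probes. With no offset 959 genes changed with Pg (494 lower), of which 914 were among the 1457, 753 changed in both infections, and 22 in opposite directions. The cause was not tested.

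Leaving out 1 array gave 2923 to 3461 changed genes for Aa, 1087 to 1372 for Pg, 1458 to 1841 for Aa against Pg and 866 to 1053 for both infections. Opposite directions ranged from 24 to 43.

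The replicate numbers do not pair the arrays: deviations of same-numbered arrays correlated at -0.051 to 0.027, and 0 of 9 arrays correlated best with their own number. With a replicate block 3309, 1303 and 1717 genes changed in the 3 comparisons, 3234, 1261 and 1673 of them also without it. It ended 8 calls of named genes, added that of Ccr7 with Aa, and ended the call of M2-associated markers with Aa (adjusted p = 0.0514, range 0.0259 to 0.0808).

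Averaging the probes of a gene kept the sign of the large changes and lowered some, such as Il23a with Aa (4.23 to 2.43), Ifi205 (4.77 to 2.70) and Nqo1 with Pg (1.53 to 0.68). Changes of Acta2, Dcn, Fas, Gbp2, Gbp5, Gsta3, Lpl, Mmp13, Nnmt, Nos2, Oasl1, Pgk1, Slc7a2, Sparc, Tcf4, Tyms and Upp1 also shrank by over 1.5 times in at least 1 comparison. Centred arrays raised the share of higher genes among those changed with Aa from 44.7% to 50.1%, and the median log2 change of all genes with Aa was 0.025 there, against -0.011. Signal over background limits the folds of dim probes: another offset moved changes of Acp5, Camp, Ctsl, Gbp5, H2-Ob, Il10, Mertk, Mgl2, Nnmt, Nos2, Nxpe4, Pltp, Pparg, Ppbp, Ptges, Ptgs2, Slamf1, Tnfsf9 and Trem3 by over 1.5 times in at least 1 comparison. Medians of called lists depend on the filter on dim probes: without it that of pro-inflammatory cytokines was 1.94 with Aa and 0.44 with Pg (main 3.89 and 1.17), and that of hypoxia genes 0.58 with Aa and 0.24 with Pg (main 0.88 and 0.51). No filter or another offset also moved by over 1.5 times, in at least 1 comparison, medians of chemokines, inflammasome, pattern recognition, eicosanoid, interferon-gamma, lipid and osteoclast genes and of dendritic cell, fibroblast, M2, macrophage and neutrophil markers. Not run were the settings that need the raw signals (normexp with offset 50, no background correction, median scaling, cyclic loess in place of quantile) and a slide block, since no slide is given in the sources used here. The deposited values, written down as an alternative, are the main source.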

Other observations

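The test of 1 scale factor was chosen before its values and after the overlap of the infections was seen.

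Genes that departed most from a proportional response were higher with Pg than the Aa response would give, such as Ppbp, Lcn2, Marco and S100a8 (by 4.62, 3.97, 2.90 and 2.58 on the log2 scale), or lower, such as Hdc (-2.04), Ifit3 (-2.04) and Il23a (-1.96). By list, oxidative stress (adjusted p = 1.83e-15), antimicrobial (1.02e-11), pattern recognition (5.57e-09) and neutrophil genes (0.000396) lay above it, and type I interferon (3.89e-11), MHC class II (4.03e-05) and maturation genes (0.0069) below.

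These values come from a test of the hypothesis that the Pg response may be a smaller version of the Aa response. With a common factor of 0.48, 769 genes (5.61%) departed from the Aa change times that factor, 409 above and 360 below, as did 11 of the 37 lists, so 1 factor did not describe all genes.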
